A study of Canis lupus familiaris with 42 samples.

How the data were processed

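RNA from canine sarcoma samples was measured on Affymetrix canine arrays, with 21 arrays before and 21 arrays after the first hyperthermia treatment. Per the labels' protocols, tissue was placed in RNAlater, RNA was extracted with a Qiagen column kit and labelled with biotin. Per the submitters' processing notes, the authors used RMA and Affymetrix Expression Console, with no version given in the sources used here. The deposited values are log2 levels, since they run from 2.13 to 14.6 with array medians between 5.20 and 5.31. The table has 43035 rows. The 111 control probe sets were left out of the tests, which leaves 42924 probe sets. Of these, 29254 have 1 gene symbol in the platform annotation, 439 have several and 13231 have none here. A current gene table was matched by gene identifier for 27680 of the 29254 and changed no symbol. Probe sets with several symbols were not named. Probe sets whose name ends in _s_at or _x_at can bind transcripts of related genes.

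Arrays were grouped by the treatment label and paired by the tumour code in the titles, as the series design describes the same tumours before and after treatment. Tumour numbers are names only. The pairing was checked by correlating arrays after removal of the group means, and all 21 pairs matched. The labels do not say whether each tumour came from a different dog, so p-values measure the spread between these tumours.

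Probe sets were tested with limma 3.58.1 in R 4.3.3, with the tumour as a block, moderated by eBayes and adjusted by Benjamini-Hochberg, two-sided, at 0.05. For genes and lists 1 probe set stood for a gene, the one with the highest mean over all arrays, which covers 15115 genes. Of 361 genes with several called probe sets, 2 had calls in both directions. The 28 gene lists were fixed before the data were examined and share no gene. For each tumour the mean change over a list's genes was taken, and its mean over tumours was tested by flipping signs, two-sided, with 100000 resamples, or all flips within batches, adjusted over the 28 lists. Camera, which compares a list with the other genes, was run with a preset correlation of 0.01 and with an estimated correlation. Relations over tumours used Pearson's r and Spearman's rho with 100000 permutations, and mclust 6.1.1 checked each list change for 2 clusters. The spread was compared by the Pitman-Morgan method with swaps within tumours. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used. The genes named were chosen by a rule written before the data were examined. It takes the 12 largest rises and the 12 largest falls among called genes that changed that way in at least 15 tumours, the 2 members of each list with the smallest p and the 2 with the largest change, a fixed set of heat, damage and inflammation genes, and the 10 expressed genes with the most variable change. Other list members are named as examples chosen after their values were seen, among them CCNG1, HSPB8, HSPA4L, CD80, CCL4, CSF1R, TIMP1 and RBBP8.

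The limma fit was tested on simulated data with the real spread of the 42924 probe sets. It recovered 40% of 50 probe sets changed by 0.25 on the log2 scale, 88% of 50 changed by 0.5, and all 50 at 1 and at 2, with 8 false calls, 4.65% of calls, and 0 calls where nothing was changed. The simulated noise was independent between probe sets, and each change was the same in every tumour. False calls among correlated probe sets were therefore not measured. Far fewer probe sets were changed than the real fit called, so recovery there may differ. The list test recovered 100 of 100 lists shifted by 0.3 and called 3 of 100 unshifted lists. Both counts are at a Benjamini-Hochberg adjusted p under 0.05 over all simulated lists. Each simulated list had an SD of change of 0.26, the median of the real lists. Lists with a larger spread, such as inflammatory cytokines and NF-kB targets (SD 0.63), were not simulated, so the recovery for them is not known.

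Alternatives fixed before the data were examined were the fit with no block, a random block, a filter at the median level, trend and robust shrinkage, array weights, renewed quantile normalisation, centring on the array median, the 3′ to 5′ contrast as a covariate, the Wilcoxon signed-rank test, 1 probe set per gene, a fold of at least 1.5, other summaries of a gene and a list, and leaving out each tumour. Alternatives added after seeing the data were each labelling batch alone, the tumours without a changed 3′ to 5′ contrast, and all tumours but 13 and 15. The batches were inferred from the poly-A controls, with the border at a level of 5.83, since no scan dates were used here.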

Results

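Gene expression was measured in spontaneous sarcomas of dogs before and after the first hyperthermia treatment, which was given beside radiotherapy. Each array held RNA from 1 tumour sample on an Affymetrix canine array, and the values are log2 levels after RMA, a method that corrects background, normalises between arrays and sums the probes of a probe set. The series describes 22 tumours. The 42 arrays analysed here came from 21 tumours, each with 1 array before and 1 array after treatment, and the tumours are numbered 1 to 21. The labels do not say how long after treatment the second sample was taken, or whether radiation had already been given. Every change below is therefore the change between the first and the second sample, with no untreated tumours sampled a second time beside it. Array medians ran from 5.20 to 5.31 on the log2 scale, and the number of arrays limits the precision.

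The arrays were divided into 2 groups, called labelling batches here, by the level of their spike-in controls. No label names a batch. The poly-A spike-in controls, bacterial transcripts added before labelling, had median levels of 7.20 before and 7.67 after treatment in 9 tumours (called the spiked batch), and of 3.55 and 3.47 in the other 12 tumours (the unspiked batch). Both arrays of a tumour always lay in the same batch. The unspiked batch was not uniform, with levels from 3.36 to 3.57 in tumours 1 to 7 and from 3.64 to 5.28 in tumours 13 to 17. It may therefore hold more than 1 batch. The 3′ to 5′ contrast of the actin and GAPDH control probe sets, a sign of RNA quality, changed by 0.13 on average (SD 0.44, n = 21). It rose in 8 of 9 spiked tumours, by a mean of 0.38, and in 5 of 12 unspiked tumours, with a mean change of -0.05.

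The first question was which genes changed between the samples. CDKN1A, the cell cycle inhibitor p21, rose in all 21 tumours, and the genes with the largest falls were mostly genes of dividing cells. Among the largest rises were MMP1, a collagenase (2.48 ± 0.57 on the log2 scale, mean ± SE, n = 21; 19 tumours higher), the macrophage scavenger receptor MARCO (1.86 ± 0.30; 19 tumours), the protease inhibitor SERPINA1 (1.54 ± 0.26; 19 tumours), TFPI2 (2.83-fold; 15 tumours), GLIPR1 (1.28 ± 0.24; 16 tumours) and S100P (1.19 ± 0.24; 17 tumours). Among the largest falls outside the proliferation list were the chaperone gene HSPA2 (-1.19 ± 0.20), the cell cycle inhibitor gene CDKN2C (-1.17 ± 0.15) and PI16 (-1.07 ± 0.19), each lower in 19 of 21 tumours. The limma adjusted p of these genes ran from 0.000141 for CDKN2C to 0.0145 for TFPI2. With each tumour as a block, limma called 2558 of 42924 probe sets at a Benjamini-Hochberg adjusted p under 0.05, 1273 higher and 1285 lower. Of 15115 named genes, each taken by 1 probe set and still adjusted over all 42924, 608 were higher and 473 were lower. The calls depended on both batches. Limma called 1293 probe sets in the spiked batch alone and 0 in the unspiked batch alone, where 4989 had an unadjusted p under 0.05. The change differed between batches at 1 probe set after adjustment, and at 3049 of 42924 by an unadjusted limma p under 0.05. Of the 1293 probe sets called in the spiked batch, 88.8% had the same sign in the unspiked batch, against 58.6% of all probe sets. Without the 5 tumours whose 3′ to 5′ contrast changed by more than 0.5, 686 probe sets were called.

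Targets of the tumour suppressor p53 rose together. The mean change of the 21 measured targets was 0.41 ± 0.26 (SD, n = 21 tumours), above 0 in 20 of 21 tumours (sign-flip permutation test, p = 1e-05, the smallest the permutations can give, and adjusted p = 0.00014 over 28 lists). CDKN1A rose by 1.85 ± 0.18 on the log2 scale, or 3.61-fold (SE, n = 21, limma adjusted p = 1.06e-05). MDM2, whose product limits p53, rose by 1.21 ± 0.16 in 19 of 21 tumours (adjusted p = 0.000141). The pro-apoptotic gene BAX (0.52 ± 0.06), CCNG1 (0.78 ± 0.09) and TIGAR (1.18 ± 0.14) were higher in all 21 tumours. In all, 8 members rose and 0 fell over all probe sets, and 12 rose and 1 fell adjusted over the list alone. In camera the list had an adjusted p = 0.0389 with an estimated correlation. The mean change was 0.57 in the spiked batch (9 of 9 tumours, exact sign-flip p = 0.00391) and 0.30 in the unspiked batch (11 of 12 tumours, exact sign-flip p = 0.00146). The difference between batches had a permutation p = 0.0142 and did not pass over the 28 lists (adjusted p = 0.303). A rise that differs in size between batches is thus not excluded.

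Proliferation genes fell. The mean change of 32 genes was -0.60 ± 0.59 (SD, n = 21 tumours), below 0 in 19 tumours (sign-flip permutation test, adjusted p = 0.00168), but the call was lost in camera with an estimated correlation (adjusted p = 0.0737). TOP2A, the topoisomerase of dividing cells, and RRM2, a subunit of ribonucleotide reductase, each changed by -1.67 (SE 0.24 and 0.25, n = 21, limma adjusted p = 0.000323 and 0.000447). The mitotic kinase CDK1 (-1.14 ± 0.19) and the motor protein gene KIF11 (-1.37 ± 0.23) fell as well. Over all probe sets 21 members fell and 1 rose. Adjusted over the list alone, 28 fell and 1 rose. The member that rose was PCNA, the sliding clamp of DNA replication (0.76 ± 0.15, adjusted p = 0.00446, 16 tumours), named here after its values were seen. The mean change was -0.80 in the spiked batch (0 of 9 tumours higher, exact sign-flip p = 0.00391). It was -0.45 in the unspiked batch (2 of 12 tumours higher, exact sign-flip p = 0.0386), which did not pass adjustment over the lists there (adjusted p = 0.123).

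**Figure D1:**
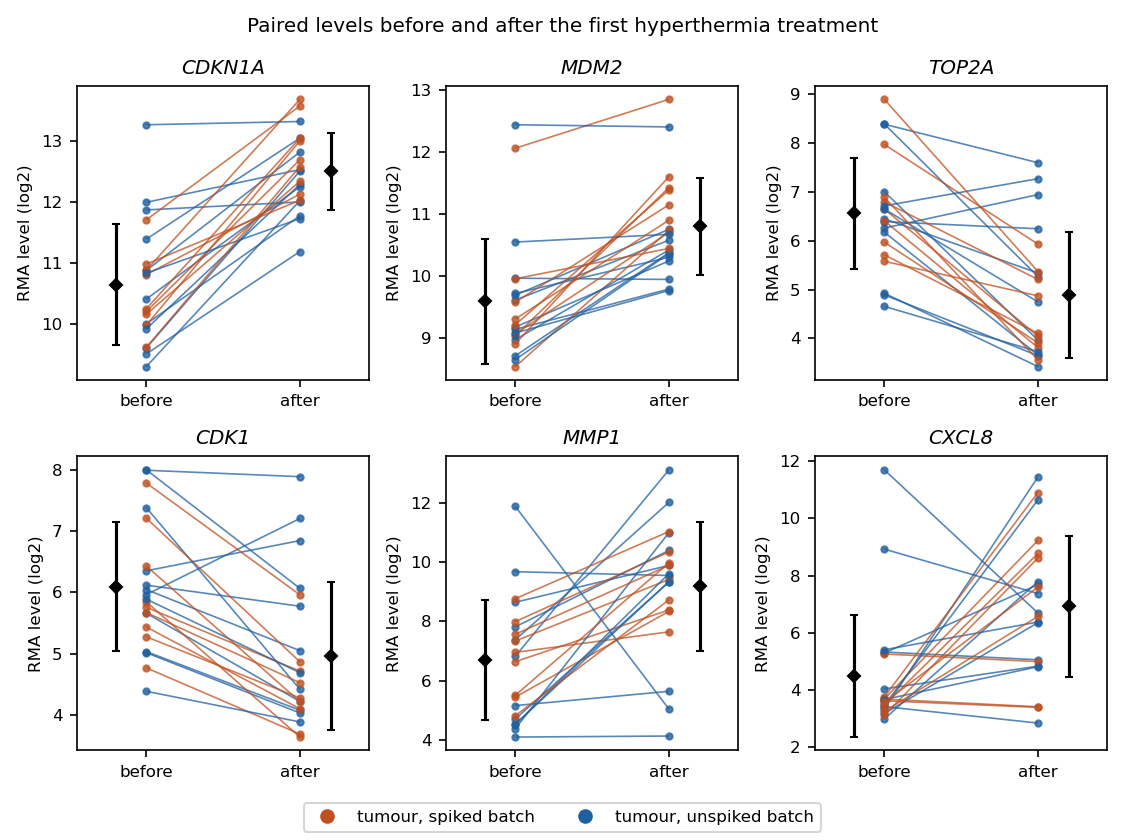
RMA levels (log2) of 6 genes before and after treatment, with 1 line per tumour (orange, spiked batch; blue, unspiked batch) and the mean ± SD of the 21 tumours as black diamonds. CDKN1A rose in all 21 tumours and TOP2A was lower in 19, while CXCL8 changed by between -4.998 and 8.11.

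The second question was which stress responses moved. Oxidative stress genes rose, with a mean change of 0.31 ± 0.23 (SD, n = 21) over 20 genes, above 0 in 20 of 21 tumours (sign-flip permutation test, adjusted p = 0.00014; camera adjusted p = 0.0389 with an estimated correlation). Among its 8 members that rose were the metallothionein MT1E (1.35 ± 0.23), the thioredoxin reductase TXNRD1 (0.55 ± 0.08, 21 of 21 tumours) and the haem oxygenase HMOX1 (0.41 ± 0.09). No member fell, and 11 rose adjusted over the list alone. The mean was 0.28 in the spiked and 0.34 in the unspiked batch. Hypoxia and HIF targets rose by a mean of 0.25 ± 0.26 over 31 genes, in 18 of 21 tumours (permutation test, adjusted p = 0.00168; camera adjusted p = 0.0737 with an estimated correlation). Of its members 12 rose and 0 fell, among them ANKRD37 (0.72 ± 0.17), the lactate transporter gene SLC16A3 (0.50 ± 0.11) and TPI1 (0.32 ± 0.06), and 18 rose adjusted over the list alone. Of the 3 probe sets of ANKRD37, 2 had a change above 0. VEGFA (0.42 ± 0.16, limma adjusted p = 0.123) and SLC2A3 (0.64 ± 0.25, limma adjusted p = 0.148) did not pass over all probe sets. The mean was 0.25 in the spiked batch (adjusted p = 0.0875, exact sign-flip test) and 0.26 in the unspiked batch.

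Genes of endoplasmic reticulum stress rose by a mean of 0.40 ± 0.60 (SD, n = 21) over 23 genes, in 15 of 21 tumours (sign-flip permutation test, adjusted p = 0.013), but the call was lost in camera with an estimated correlation (adjusted p = 0.425). EDEM1 (1.16 ± 0.28), asparagine synthetase ASNS (1.002 ± 0.29) and the chaperone HSPA5 (0.56 ± 0.14) were among 5 members that rose, and 15 rose adjusted over the list alone. The call on ASNS was lost in 8 of the 21 fits that left out 1 tumour. The list passed in neither batch alone, with means of 0.33 and 0.45. The 21 heat shock chaperones did not pass as a list, with a mean change of 0.17 ± 0.37 and 13 tumours higher (permutation test, adjusted p = 0.124). In camera they passed with the preset correlation of 0.01 (adjusted p = 0.00655) but not with an estimated correlation of 0.377 (adjusted p = 0.612). Their mean was 0.06 in the spiked batch (5 of 9 tumours higher) and 0.25 in the unspiked batch (8 of 12 tumours higher, exact sign-flip test, adjusted p = 0.123), and the difference between batches did not pass (permutation test, adjusted p = 0.639). CRYAB (1.14 ± 0.22, limma adjusted p = 0.00358), BAG3 (0.77 ± 0.21), HSPB8 (0.47 ± 0.13) and HSPA4L (0.37 ± 0.11) rose while HSPA2 fell, and adjusted over the list alone 7 rose and 1 fell. The call on BAG3 was lost in 2 of the fits that left out 1 tumour. The changes of HSPB1 (0.01 ± 0.06), HSP90AA1 (0.11 ± 0.07), DNAJB1 (0.20 ± 0.20) and HSPH1 (0.47 ± 0.24) did not pass, and the sign of HSPB1 turned under array weights, renewed quantile normalisation and the 3′ to 5′ covariate. HSPA1A and MKI67 were not analysed here. Immediate early genes did not pass as a list (0.21 ± 0.60, adjusted p = 0.235), although FOSL1 (0.73 ± 0.12) and ATF3 (0.88 ± 0.22) rose. FOS (0.38 ± 0.30) and EGR1 (0.12 ± 0.23) did not pass. The apoptosis regulators passed with a small mean of 0.09 ± 0.12 (16 tumours higher, adjusted p = 0.00804; camera adjusted p = 0.439 with an estimated correlation) but in neither batch alone, and only BCL2A1, an anti-apoptotic member of the BCL2 family, rose (1.27 ± 0.28).

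**Figure D2:**
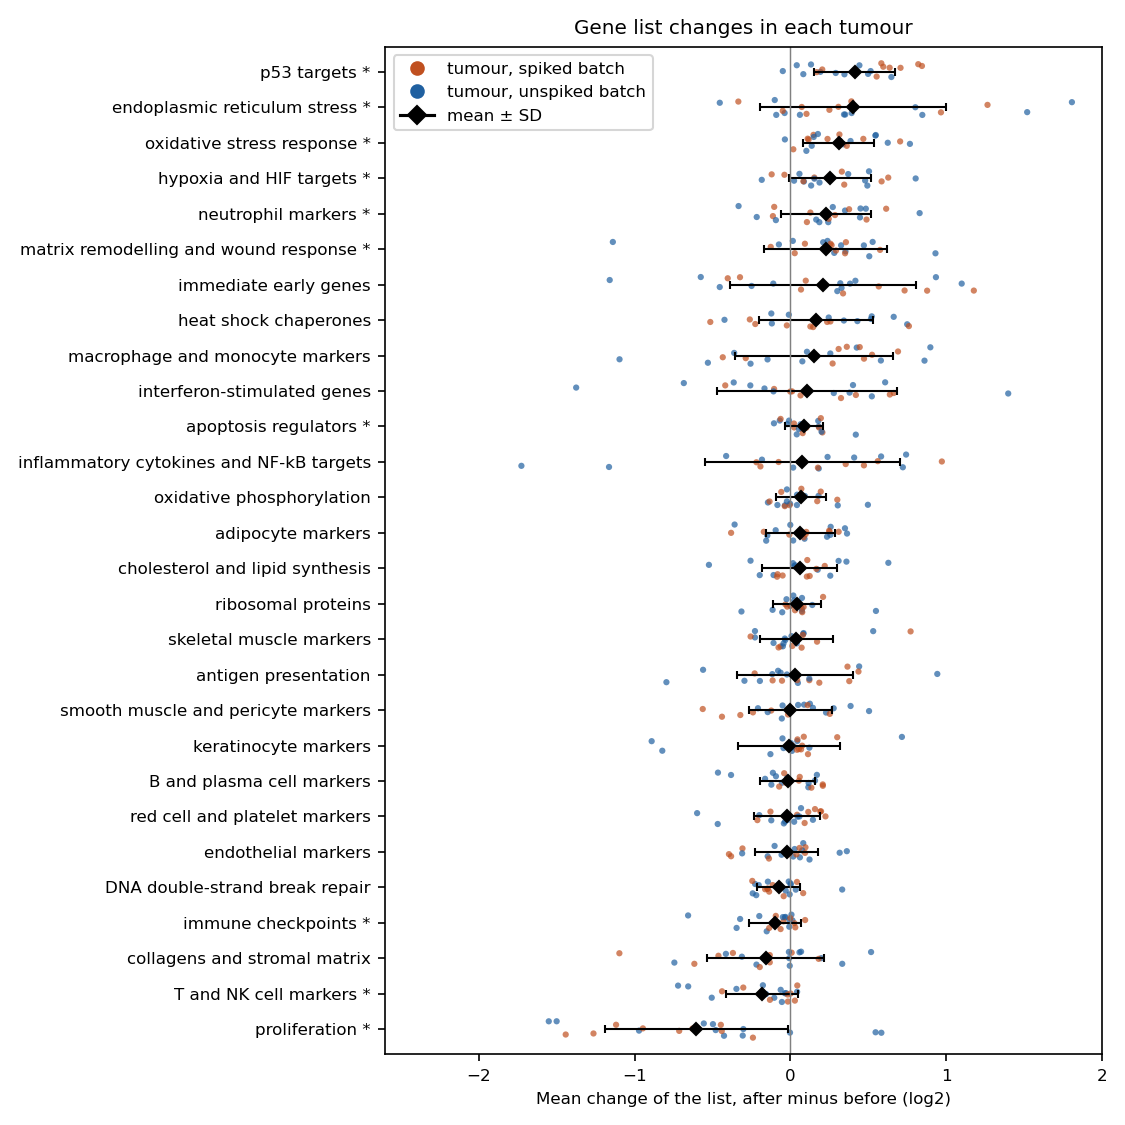
Change of each of the 28 gene lists in each of the 21 tumours (log2, after minus before; orange, spiked batch; blue, unspiked batch), with the mean ± SD over tumours as black diamonds and a star beside lists with an adjusted p under 0.05. The mean of p53 targets was 0.41 and that of proliferation genes -0.60.

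Markers of immune cells moved apart. T and NK cell markers fell by 0.18 on average, a mean change of -0.18 ± 0.23 (SD, n = 21) over 30 genes, with 4 tumours higher (sign-flip permutation test, adjusted p = 0.00168; camera adjusted p = 0.196 with an estimated correlation). The 11 members that fell included the granzyme GZMA (-0.61 ± 0.12), the kinase LCK (-0.44 ± 0.10) and CD3D (-0.57 ± 0.15), and 11 fell adjusted over the list alone. Some of them lay at low levels, with means before treatment of 4.601 for GZMA and 4.94 for LCK, against a median probe set mean of 5.28. With genes above that median alone the list did not pass (mean change -0.10, adjusted p = 0.164). The mean was -0.11 in the spiked batch (adjusted p = 0.182, exact sign-flip test) and -0.23 in the unspiked batch. Neutrophil markers rose by a mean of 0.23 ± 0.29 over 18 genes, in 16 of 21 tumours (permutation test, adjusted p = 0.00804; camera adjusted p = 0.196 with an estimated correlation). The receptor TREM1 (0.61 ± 0.13), lipocalin LCN2 (0.82 ± 0.22) and the calprotectin subunit S100A9 (1.08 ± 0.32) rose, and 6 members rose adjusted over the list alone. The neutrophil list lay at a low level too, with a mean of 4.74 before treatment. The call on S100A9 was lost in 15 of the 21 fits that left out 1 tumour, and that on LCN2 in 6. Within batches the mean was 0.23 in both and passed in neither after adjustment.

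Immune checkpoint genes passed with a mean of -0.10 ± 0.17 and 6 tumours higher (permutation test, adjusted p = 0.013; camera adjusted p = 0.332 with an estimated correlation). The mean was -0.03 in the spiked batch (4 of 9 tumours higher, exact sign-flip test, adjusted p = 0.276) and -0.15 in the unspiked batch (2 of 12 tumours higher, adjusted p = 0.0355), and the difference between batches did not pass (permutation test, adjusted p = 0.462). IDO2 (-0.41 ± 0.09) and CD80 (-0.41 ± 0.10) fell and SIRPA rose (0.32 ± 0.06). Macrophage and monocyte markers did not pass as a list (0.15 ± 0.51, adjusted p = 0.306). MARCO and the Fc receptor FCGR1A (0.81 ± 0.18) were among 4 members that rose, and CSF1R fell (-0.49 ± 0.15). Adjusted over the macrophage list alone 9 rose and 5 fell. Inflammatory cytokines and NF-kB targets did not pass (0.08 ± 0.63, adjusted p = 0.748), and the median over its members was -0.06, opposite in sign to the mean, as was its direction in camera (lower, adjusted p = 0.868 with an estimated correlation). CXCL8, a neutrophil attractant, rose (2.44 ± 0.67, limma adjusted p = 0.0303, 14 tumours higher), as did SOD2 (0.87 ± 0.24), while the T cell attractants CXCL10 (-0.96 ± 0.26, 19 tumours lower) and CCL4 (-0.82 ± 0.23) fell. Of the 21 fits that left out 1 tumour, the call on CXCL8 was lost in 9, that on SOD2 in 7 and that on CXCL10 in 1. IL6 (0.77 ± 0.38) and PTGS2 (1.06 ± 0.45) did not pass. Interferon-stimulated genes (0.11 ± 0.58, adjusted p = 0.575), antigen presentation (0.03 ± 0.37, adjusted p = 0.797) and B and plasma cell markers (-0.02 ± 0.18, adjusted p = 0.777) did not pass.

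Matrix remodelling and wound response genes passed narrowly, with a mean of 0.23 ± 0.39 (SD, n = 21) over 29 genes and 18 tumours higher (sign-flip permutation test, adjusted p = 0.0416; camera adjusted p = 0.775 with an estimated correlation). MMP1, osteopontin SPP1 (0.999 ± 0.25) and the inhibitor TIMP1 (0.77 ± 0.20) were among 5 members that rose. Adjusted over the list alone 8 rose and 3 fell, and the median change of its members was 0.09. The call was lost in 14 of the 21 tests that left out 1 tumour, and the list passed in neither batch alone. Collagens and stromal matrix did not pass (-0.16 ± 0.37, adjusted p = 0.132), although 4 members fell, among them COL6A3 (-0.43 ± 0.11) and FBLN5 (-0.42 ± 0.09). That list passed without tumour 15 (-0.193, permutation test, adjusted p = 0.0479). In camera it passed with the preset correlation (adjusted p = 9.955e-06) but not with an estimated correlation (adjusted p = 0.439). DNA double-strand break repair did not pass (-0.07 ± 0.14, adjusted p = 0.061), although it did without tumour 8 (adjusted p = 0.0435) or tumour 15 (adjusted p = 0.0034), with 5 members lower, such as FANCI (-0.34 ± 0.07), and RBBP8 higher. Its change went with that of proliferation genes over the 21 tumours (r = 0.697, a relation examined after the results were seen). Oxidative phosphorylation did not pass (0.07 ± 0.16, adjusted p = 0.129), with 4 members higher, such as NDUFS8 (0.46 ± 0.08). The lists of ribosomal proteins (0.04 ± 0.16), cholesterol and lipid synthesis (0.06 ± 0.24), endothelial (-0.02 ± 0.20), skeletal muscle (0.04 ± 0.24), keratinocyte (-0.01 ± 0.33), adipocyte (0.07 ± 0.22) and red cell and platelet markers (-0.02 ± 0.21) did not pass. The keratinocyte list turned its sign and passed in the spiked batch (0.0896, exact sign-flip test, adjusted p = 0.0273). It also did so without tumours 13 and 15 (0.0798, sign-flip permutation test, adjusted p = 0.0334). Smooth muscle and pericyte markers had a mean change of 0.0006 ± 0.27 and did not pass.

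The title of the series names heterogeneity of the response, and the tumours differed widely. The root mean square change over all probe sets ran from 0.2501 in tumour 5 to 0.542 in tumour 15, and the number of probe sets changed at least 2-fold from 59 in tumour 5 to 2168 in tumour 13. CDKN1A changed by 0.05 in tumour 14, 0.13 in tumour 5 and 3.01 in tumour 10. The proliferation list changed by 0.55 in tumour 13 and 0.59 in tumour 15, against -1.55 in tumour 4. CXCL8 changed by 8.11 in tumour 7 and -4.998 in tumour 15, where MMP1 changed by -6.84. The levels before treatment differed as well. CXCL8 was at 3.34 in tumour 7 and 11.7 in tumour 15 (mean 4.49), and MMP1 at 11.9 in tumour 15 (mean 6.70). CDKN1A was at 13.3 in tumour 14 (mean 10.7). A low or high start limits how far a level can move, so such differences need not be of response alone. Tumours 13 and 15 had the lowest array weights (0.426 and 0.402). In the paired fit both arrays of a tumour got the same weight. A low weight thus reflects how far the tumour's change lay from the mean change, and is no separate sign of quality. In tumour 13 the 3′ to 5′ contrast changed by -1.03, and the poly-A controls on its array before treatment were at 5.28. After the group means were removed, all 21 arrays after treatment correlated best with the array of their own tumour before treatment. That correlation over probe sets, which are not independent replicates, averaged 0.684 and ran from 0.438 to 0.900, against a mean of -0.025 with other tumours (permutation p = 1e-05, the smallest the permutations can give). The ER stress list had the widest range of the lists that passed, from -0.45 in tumour 6 to 1.81 in tumour 1.

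**Figure D3:**
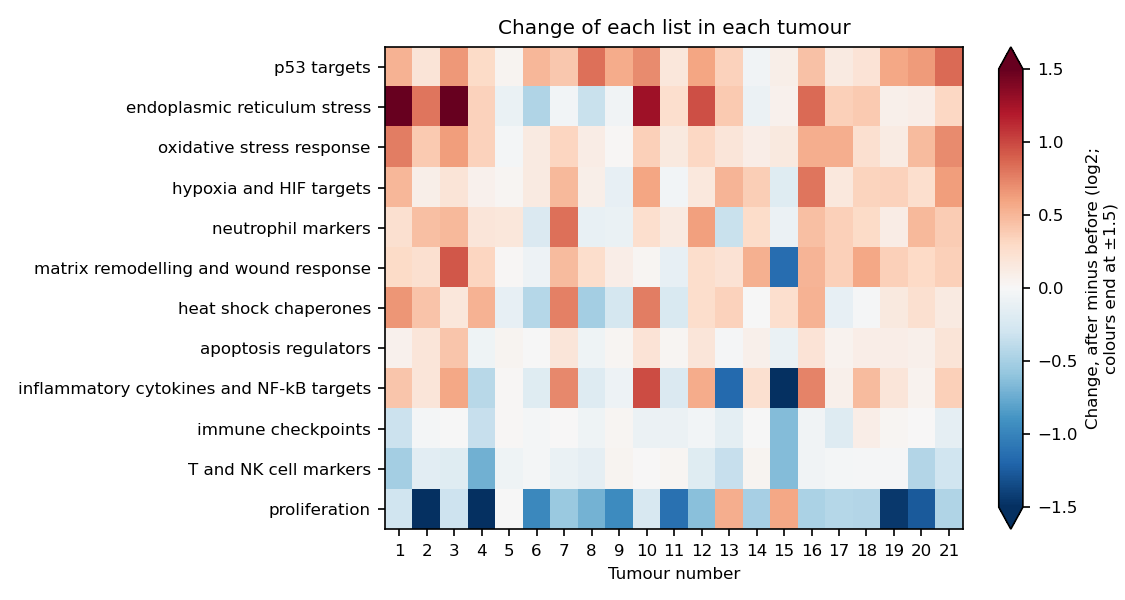
Change (log2, after minus before) of the 10 lists that passed, with heat shock chaperones and inflammatory cytokines added, in each of the 21 tumours (colour scale ending at ±1.5). Proliferation was higher after treatment in 2 tumours, numbers 13 and 15.

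Of 45 relations between the changes of 10 lists over the 21 tumours, 1 passed adjustment. Inflammatory cytokines and NF-kB targets changed with neutrophil markers (Pearson r = 0.704, permutation p = 0.00027, adjusted p = 0.0122; Spearman rho = 0.736, permutation p = 0.00031, adjusted p = 0.014). Without the 2 tumours farthest from the median of the inflammatory change r was 0.639. Within batches r was 0.543 in the 9 spiked and 0.790 in the 12 unspiked tumours. Pairs of random lists gave a median r of 0.088, with 95% of pairs between -0.494 and 0.583. These were matched in size and expression to heat shock chaperones and proliferation, not to the inflammatory and neutrophil lists, so they are only a rough background. None of 10 relations between a list's level before treatment and the heat shock change passed adjustment (lowest adjusted permutation p = 0.336 by r and 0.2405 by rho, both for the level of the heat shock list itself, which regression to the mean biases downward).

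**Figure D4:**
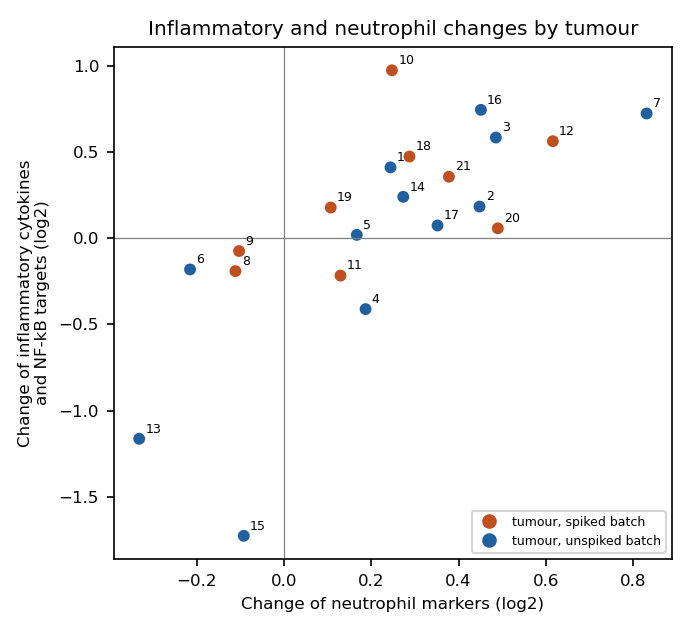
Change of inflammatory cytokines and NF-kB targets against change of neutrophil markers (both log2, after minus before), with 1 point per tumour, numbered (orange, spiked batch; blue, unspiked batch). The 21 tumours gave r = 0.704, and tumours 13 and 15 lie lowest.

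Whether tumours became more or less alike was tested with the paired variances of each list. In 0 of 28 lists did the spread between tumours change after adjustment (Pitman-Morgan comparison, permutation test). This depended on the processing, since with the mean of all probe sets of a gene B and plasma cell markers and immune checkpoints passed (adjusted p = 0.0293 and 0.0146), and without tumour 2 keratinocyte markers did (adjusted p = 0.00196). The smallest adjusted p was 0.116, for B and plasma cell markers, whose SD was 0.31 before and 0.17 after treatment. The SD of ER stress genes was 0.24 before and 0.51 after treatment (adjusted p = 0.17).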

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

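The alternatives with 1 labelling batch, without tumours of changed 3′ to 5′ contrast and without tumours 13 and 15 were chosen after seeing the data. The cause was not tested for any change below unless it is given. Against 2558 called probe sets (1273 higher, 1285 lower), the fit with no replicate block called 30 (27 higher, 3 lower), since the spread between tumours then enters the error. The random block called 1791, with 663 lower. With 1 probe set per gene 1189 were called (667 and 522), from fewer tests, and with a fold of at least 1.5 added 377 (201 and 176). The spiked batch alone gave 1293 (510 and 783), the unspiked batch alone 0 (0 higher, 0 lower, with 4989 at an unadjusted limma p under 0.05), where the spread of the change was 1.33 times that of the spiked batch at the median probe set. Without the 5 tumours of changed contrast 686 were called (269 and 417), from fewer tumours. Without tumours 13 and 15, 3861 were called (1658 and 2203). Those 2 had the lowest array weights, which mark changes unlike the mean change, so more calls without them are no surprise. The other alternatives stayed within 1.5 times. Leaving out 1 tumour gave 1816 (without 10) to 3171 (without 15) called probe sets, 882 to 1587 higher and 920 to 1730 lower.

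Of the 28 lists 10 passed, 7 higher and 3 lower. In camera with an estimated correlation only p53 targets and oxidative stress passed (adjusted p = 0.0389 for both), and the other 8 lists did not (adjusted p from 0.0737 to 0.775). With the preset correlation of 0.01, below every estimated one, camera did not pass apoptosis regulators or matrix remodelling (adjusted p = 0.196 for both). It then passed some lists that the sign-flip test did not. Among them were heat shock chaperones (adjusted p = 0.00655), collagens (lower, adjusted p = 9.955e-06) and oxidative phosphorylation (adjusted p = 0.00558). In the spiked batch alone 4 passed (3 higher, 1 lower) and in the unspiked batch alone 5 (3 higher, 2 lower), from fewer tumours. Without tumours 13 and 15, 15 passed (10 higher, 5 lower). Leaving out 1 tumour gave 9 to 12 lists, 6 to 8 higher and 3 to 5 lower (5 without tumour 15, where collagens and double-strand break repair passed as well). Double-strand break repair also passed without tumour 8 (-0.0823, adjusted p = 0.0435), with the mean of all probe sets of a gene (-0.0782, adjusted p = 0.0299) and with the most variable probe set (-0.0973, adjusted p = 0.0325). The p53 change stayed past the threshold under every alternative run, and ran from 0.39 to 0.44 when 1 tumour was left out. Proliferation ran from -0.66 to -0.56 and lost its call in the unspiked batch alone (-0.45, adjusted p = 0.123). Heat shock ran from 0.14 to 0.20, and passed without tumour 8 (0.20, adjusted p = 0.0437). The matrix remodelling list lost its call without any 1 of tumours 1, 2, 3, 4, 7, 12, 13, 14, 16, 17, 18, 19, 20 and 21 (0.19 to 0.23), and kept it without tumour 15 (0.295). The spread changed in 2 lists with the mean of all probe sets of a gene, B and plasma cell markers (adjusted p = 0.0293) and immune checkpoints (adjusted p = 0.0146), and in 1 list without tumour 2, keratinocyte markers (adjusted p = 0.00196; 0 to 1 when 1 tumour was left out). All 21 arrays matched their own tumour, and 1 relation passed, under both alternatives run for each.

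Signs turned only in results that did not pass as first tested. The smooth muscle list had -0.0072 with the most variable probe set, -0.0025 by the median over genes, -0.003 after renewed quantile normalisation, -0.0064 without tumours 13 and 15 and -0.149 in the spiked batch. The inflammatory list had -0.0766 by the median over genes and -0.0424 in the unspiked batch. The keratinocyte list had 0.0777 above the median level, 0.0221 without tumours of changed contrast, and passed at 0.0798 without tumours 13 and 15 (adjusted p = 0.0334) and at 0.0896 in the spiked batch (adjusted p = 0.0273). Without tumours of changed contrast, without tumours 13 and 15 and in the spiked batch, B and plasma cell markers had 0.0188, 0.0273 and 0.0571, and red cell and platelet markers 0.0055, 0.0329 and 0.0765. In the unspiked batch antigen presentation had -0.047 and endothelial markers 0.0385. HSPB1 had -0.0056 with array weights, -0.0094 after renewed quantile normalisation, -0.0178 with the 3′ to 5′ covariate and -0.0323 in the spiked batch. In the spiked batch IDO1 had 0.0783, IVL 0.0084 and LUM -0.238, and in the unspiked batch EGR1 -0.105 and RGS5 0.133. NR4A1 had 0.0187 without tumours of changed contrast and 0.130 without tumours 13 and 15, where ALAS2 had 0.0426. When 1 tumour was left out, antigen presentation ran from -0.0183 to 0.0687, B and plasma cell markers from -0.0268 to 0.0069, smooth muscle from -0.0247 to 0.0287, keratinocyte from -0.0456 to 0.0347, red cell and platelet from -0.0333 to 0.008, HSPB1 from -0.0146 to 0.0327 and NR4A1 from -0.222 to 0.066. Of 62 called named genes, 49 kept the call without any 1 tumour. With the 3′ to 5′ covariate 50 of the 62 kept it, and without the tumours of changed contrast 31 did. In the spiked batch alone 45 kept it and in the unspiked batch alone 0, both from fewer tumours.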

Other observations

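Apart from the RNA quality tests and the tests of single genes and of whole lists over the 21 tumours, the tests in this part were chosen after the results were seen, as was the use of the neutrophil list against a lower share of leukocytes. PCNA, a p53 target as well as a replication gene, rose by 0.76 ± 0.15 (SE, n = 21) while 21 other proliferation genes fell. Among all 300 pairs of the 25 lists whose changes did not fall into 2 clusters, 23 passed by r and 8 by both r and rho. The ER stress change went with the oxidative stress change (r = 0.705, permutation p = 0.00035, adjusted p = 0.015; rho = 0.757, permutation p = 0.00015, adjusted p = 0.0075). Without the 2 tumours farthest from the median r was 0.522, and it was 0.361 in the 9 spiked and 0.864 in the 12 unspiked tumours. The relation of the ER stress change with the heat shock change passed narrowly by r (r = 0.619, permutation p = 0.00261, adjusted p = 0.0489) and did not pass by rho (rho = 0.630, permutation p = 0.0028, adjusted p = 0.0646), with r of 0.5003 without the 2 farthest tumours, 0.839 in the spiked and 0.508 in the unspiked batch. The macrophage change went with that of antigen presentation (r = 0.807, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.003; rho = 0.831, permutation p = 1e-05, adjusted p = 0.0015), with r of 0.687 without the 2 farthest tumours, 0.719 in the spiked and 0.821 in the unspiked batch. Double-strand break repair changed with proliferation by r (r = 0.697, permutation p = 0.0004, adjusted p = 0.015) but did not pass by rho (rho = 0.625, permutation p = 0.00315, adjusted p = 0.0675). There r was 0.528 without the 2 farthest tumours, 0.563 in the spiked and 0.732 in the unspiked batch. The lower level of repair genes therefore cannot be read as separate from that of proliferation genes.

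Chance swaps do not account for the number of calls. Among 100 splits that swapped before and after within tumours, the real one included, 1 gave as many called probe sets as the real 2558, and the highest of the others was 0.

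The rise of p53 targets and the fall of proliferation genes were weighed against RNA quality and the labelling batch. The fall did not pass in camera with an estimated correlation (adjusted p = 0.0737). With the 3′ to 5′ contrast as a covariate the p53 change was 0.41 (0.4091) and the proliferation change -0.52, both past adjustment (adjusted p = 0.00028 and 0.00482), which argues against RNA quality as the whole cause. The p53 change in the unspiked batch, 0.30 (adjusted p = 0.0182), argues against an effect of 1 batch. For proliferation the batch stays open, since the unspiked change of -0.45 passed only before adjustment (exact sign-flip p = 0.0386, adjusted p = 0.123). This test was first set at the unadjusted p, by which the batch would have been argued against, and was moved to the adjusted p afterwards. The 2 of 12 unspiked tumours that rose were 13 and 15. Without both the change over the other 19 tumours was -0.73 (sign-flip permutation test, adjusted p = 0.000187). Leaving out the only tumours that rose makes a larger fall certain, and the 19 include all spiked tumours. This value therefore does not bear on the batch. A link in which tumours with more p53 activity stop dividing more stays open too, since r between the changes was -0.17 over 21 tumours (permutation p = 0.456; rho = -0.134, permutation p = 0.56; 95% interval -0.562 to 0.280; r without the 2 farthest tumours -0.089, 0.202 in the spiked and -0.123 in the unspiked batch). The p53 rise may be a response to treatment, but radiation and heat were not separated here.

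The fall of T and NK cell markers beside the rise of neutrophil markers was weighed next. A lower share of all leukocytes would lower both, while the neutrophil list rose by 0.23 (0.2303, sign-flip permutation test, adjusted p = 0.00804). That rise is part of the pattern being weighed, so it is no separate test of such a share. The rise passed in neither batch alone, and in camera it did not pass with an estimated correlation (adjusted p = 0.196). The fall of T and NK markers did not pass in camera with an estimated correlation (adjusted p = 0.196), in the spiked batch (adjusted p = 0.182) or with genes above the median level alone (adjusted p = 0.164). With the 3′ to 5′ covariate the changes were -0.19 and 0.19 (adjusted p = 0.00371 and 0.0126), which argues against RNA quality as the whole cause. Whether cells moved or changed their expression was not tested.

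The rise of CXCL8 and MMP1 was weighed last. Keratinocytes in the second sample stay open. Of 18 keratinocyte markers at low levels before treatment, the highest upper 95% limit of the mean change was 0.75 (0.746, SBSN), under the lower limits of CXCL8 (0.90) and MMP1 (1.16). Markers at such low levels exclude little, and the keratinocyte list rose in 9 of 9 spiked tumours, though only by 0.09 (0.0896, exact sign-flip test, adjusted p = 0.0273). It also passed without tumours 13 and 15 (0.0798, sign-flip permutation test, adjusted p = 0.0334). Those 2 had the largest falls of the list (-0.89 and -0.82). Leaving them out favours a rise, so that value does not bear on keratinocytes. The CXCL8 change went with the neutrophil change (r = 0.794, permutation p = 2e-05; rho = 0.817, permutation p = 1e-05, the smallest the permutations can give; r = 0.747 without the 2 farthest tumours, 0.746 in the spiked and 0.852 in the unspiked batch; adjusted p = 6e-05 over 3 relations). Neutrophil influx is thus a candidate explanation for the rise of CXCL8, but r gives no direction. Since CXCL8 attracts neutrophils, a rise of CXCL8 that came first would give the same r. Whether the MMP1 change went with the neutrophil change was not tested. The CXCL8 relation is not independent of the list relation in the report, since CXCL8 is a member of the inflammatory list, and without it that list still gave r = 0.665 (permutation p = 0.00077; rho = 0.695, permutation p = 0.00081). A wound response to the first biopsy cannot be told apart from treatment, since 0 tumours were sampled a second time without treatment.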
